A study of Rattus norvegicus with 6 samples.

How the data were processed

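RNA was measured in 6 libraries labelled as primary cultured rat (Rattus norvegicus) microglia, 3 kept for 24 h with IR-813 and 3 with PSNPs. Per the labels' protocols, microglia were shaken loose from mixed co-cultures, RNA was isolated with a column kit, polyadenylated RNA was selected, and libraries were made with a kit that is not stated to keep strand information. Groups and replicate numbers were taken from the sample titles. The deposited tables name their columns con for the libraries whose titles give IR-813 and NPS for those whose titles give PSNPs, each with the replicate number, and they were joined through the sample that each per-library file belongs to. Whether con stands for a control other than IR-813 is not given in the sources used here, and the title was followed. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The labels give no dose, no batch and no untreated sample, and no library labelled untreated was analysed here.

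The authors deposited a table of whole-number read counts per gene symbol for all 6 libraries, and this table was the main source. The submitters' processing notes name bcl2fastq and the genome build mRatBN7.2. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Reads that a gene shares with a near-identical copy, an overlapping gene or an antisense partner could therefore not be assigned with certainty. The authors also deposited 1 file per library with log2 values, whose scaling is not stated per the labels. With a pseudocount of 1 removed, the unlogged value was proportional to the count within 0.05 log2 units, once a gene factor and a library factor were allowed, for 98.0% of genes in the library with the lowest share. Of 101256 cells, 12 held a log2 value above 0 with a count of 0. The gene factor was used as a proxy for transcript length. It was available for 92.5% of the tested genes. It lay at or below the gene's span in the reference table for 99.6% of the 10061 genes with both. A span also covers introns, so this is a weak check of a transcript length. The Spearman correlation of the proxy with the span across genes, which are not independent replicates, was 0.507. Among the 490 genes with a span under 3000 bp it was 0.362.

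The count table held 16876 gene symbols, of which 2858 had a count of 0 in every library. The reference table of gene names is of assembly GRCr8, a different build, so it was used for names and spans only and no coordinates are given. It held 14386 of the symbols, and 2104 of the other 2490 were synonyms in it. Total counts ranged from 19166605 to 22553507 per library. The ribosomal RNA genes Rn28s, Rn18s and Rn45s together took between 0.310% and 1.56% of the counts.

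Counts were filtered with filterByExpr, which left 11679 genes, scaled with TMM factors, and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) with the treatment as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. Levels are CPM on the TMM-scaled library sizes, as mean ± SD over 3 libraries. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.159. Reads without molecular identifiers are not independent molecules. For single values the smallest p of an exact 2-sided test of 3 against 3 is 0.1, so no such test was used.

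Before the data were examined, 31 gene lists were written down from the cell type and the exposure. Lists with at least 5 tested members (29 lists) were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The list of sex-linked genes, with 3 tested members, and the list of infiltrating myeloid and lymphoid markers, all of them under the count filter, were not tested as sets. Listed genes that the count table did not hold, also under a synonym, were not analysed here. Each list was also tested with an estimated correlation and with fry, a test of whether the genes of a list move in 1 direction on balance. Unlike camera, fry does not compare a list with the other genes. Where many genes differ, a list can therefore pass fry without standing out from the rest. Cell type markers were used to give levels in each library.

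Named genes followed a rule that was also fixed before the data were examined. It takes the 12 largest and the 12 smallest log2 fold changes among called genes with an official symbol, a mean of at least 5 CPM in either group and no overlap between the 2 groups of libraries. It adds the 4 members with the smallest p of each list that passed camera, the 2 members with the smallest p of every other list as values, and 11 markers of microglial inflammation and identity (Il1b, Il6, Tnf, Ccl2, Nos2, Cx3cr1, P2ry12, Tmem119, Trem2, Cd68 and Aif1). Genes named outside the rule are marked where they occur, and some genes that the rule takes are not reported here.

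Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile, library size only), DESeq2 1.42.0, limma-voom, other count filters, the replicate number as a block, a test against a 1.5-fold change, an adjusted p under 0.01, leaving out each library, and limma on the deposited log2 values. A per-library offset along the length proxy (lowess with a span of 0.3) and a fit without the ribosomal RNA genes were added after the data had been seen. The pairs of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom between 4.15 and 87.7, so every library was counted.

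The tests were first run on simulated counts drawn for the 11679 genes from the real means, library sizes and dispersions, with 100 genes changed 2-fold and 100 changed 1.5-fold. The edgeR test recovered 73.0% of the 2-fold and 15.0% of the 1.5-fold changes, and 3.30% of its calls were unchanged genes. The median estimate for a log2 fold change of 1 was 0.98. Of the lists, camera called the 1 that had been shifted and 1 that had not. A length trend put into 1 library gave a Spearman correlation of −0.451 between length proxy and fold change, and −0.00665 after the offset.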

Results

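Transcripts were counted in libraries labelled as primary cultured rat microglia after 24 h with PSNPs, polystyrene nanoplastics, or with IR-813, a near-infrared dye that served as the comparison, in 3 libraries each. The deposited tables name the columns of the IR-813 libraries con, and whether this stands for a control other than IR-813 is not given in the sources used here. The comparison asks which transcripts of these cells differ between PSNPs and IR-813, in a study of behaviour and neuronal activity. No library labelled untreated was analysed here, so a rise or fall means higher or lower with PSNPs than with IR-813. Which treatment moved a gene cannot be told. The astrocyte gene Gfap and the myelin gene Mbp ranked among the most abundant genes in each library, above the microglia genes Aif1, Cx3cr1 and P2ry12. The IR-813 libraries held 21920602, 21039765 and 20837099 counts and the PSNPs libraries 22553507, 19166605 and 19646895 counts, and between 13001 and 13255 genes were detected per library. The first principal component, with 77.4% of the variance, separated the treatments. The second, with 15.6%, set PSNPs replicate 3 (35.4) apart from PSNPs replicates 1 and 2 (−22.9 and −24.3). The correlation of log CPM across genes was 0.995 between PSNPs replicates 1 and 2 and at most 0.974 between either of them and replicate 3.

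As lists tested by camera with a preset correlation, heat-shock genes, neuron, oligodendrocyte-lineage and homeostatic microglia genes and genes of the unfolded-protein and integrated stress response (17 lower and 7 higher of 31) were lower with PSNPs. Genes of MHC antigen presentation (17 higher and 0 lower of 22), interferon-response genes (9 and 1 of 32) and NRF2 oxidative-stress genes (16 and 6 of 29) were higher. The interferon list did not pass by fry, and the NRF2 list did not pass camera with the length offset. With an estimated correlation 0 of 29 lists passed camera (smallest adjusted p = 0.455, with 1 list at an unadjusted p under 0.05), while 17 passed fry. Fry does not compare a list with the other genes, of which many differed here, so its passes do not offset the result of camera. The inducible heat-shock gene Hspa1b fell from 2903 ± 657 CPM with IR-813 to 13.02 ± 1.11 CPM with PSNPs (SD, n = 3 each). Trib3, a pseudokinase gene of the stress response, fell from 64.0 ± 12.9 to 3.31 ± 0.903 CPM. The detoxification enzyme gene Nqo1 rose from 392 ± 50.1 to 899.6 ± 91.0 CPM, and the MHC class II chaperone gene Cd74 from 2.29 ± 0.889 to 12.6 ± 2.38 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2439 of 11679 genes were higher and 2351 were lower with PSNPs. More than 2-fold changes were found for 545 of the higher and 1029 of the lower genes.

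All 3 PSNPs libraries lay on the same side of all 3 IR-813 libraries for 2429 of the higher and 2348 of the lower genes. For the called genes this follows largely from the call itself. It also held for 61.4% of all tested genes, where chance gives 10% for a single gene. Genes of a library move together, so that share is no test of the treatment. Scaling by library size alone gave 1943 higher and 2852 lower genes, so that 40.5% of the calls were higher in place of 50.9%. Without IR-813 replicate 1 there were 1416 higher and 1571 lower genes, and without IR-813 replicate 2 there were 1339 and 1473. Without PSNPs replicate 3, the library that stood apart, there were 3591 and 3478.

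Among the genes with the largest increases were several enzymes of small-molecule metabolism. Mgst2, a microsomal glutathione S-transferase, rose by 4.60 ± 0.31 on the log2 scale (estimate ± SE) and Ptgr1, a prostaglandin reductase, by 3.09 ± 0.20. Hsd11b2, which inactivates corticosterone, rose by 4.26 ± 0.21, Dio2, which activates thyroid hormone, by 3.44 ± 0.57, and Slc47a1, an organic cation exporter, by 3.28 ± 0.21. Dio2 stood at 66.8 and 53.9 CPM in PSNPs replicates 1 and 2 and at 13.2 CPM in replicate 3, against 4.11 ± 0.0371 CPM with IR-813. The secreted or surface proteins in this group were Pnoc (prepronociceptin, 4.25 ± 0.18), Cd36 (a scavenger receptor for fatty acids, 3.96 ± 0.36), Sfrp5 (a Wnt antagonist, 4.33 ± 0.38), Serpina3n (a protease inhibitor, 3.58 ± 0.37), Mmp11 (a matrix metalloproteinase, 3.25 ± 0.09) and Pinlyp (4.87 ± 0.39).

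The largest decreases included stress genes and genes of neurons. Hspa1a fell by 8.02 ± 0.33 and Hspa1b by 7.80 ± 0.24 on the log2 scale, and as near-identical copies their split is uncertain. Cryab, a small heat-shock protein gene, fell by 4.40 ± 0.27, Abcb1a, which encodes the efflux pump P-glycoprotein, by 5.76 ± 0.37, and Thbs1, a matrix glycoprotein gene, by 4.20 ± 0.23. Shank1 (a postsynaptic scaffold, −4.94 ± 0.32), Slc4a10 (a bicarbonate transporter, −4.44 ± 0.39), Gad1 (GABA synthesis, −4.19 ± 0.17), Cacna1i (a T-type calcium channel, −4.13 ± 0.40), Slitrk1 (a neuronal membrane protein, −4.01 ± 0.26) and Runx1t1 (a transcriptional corepressor, −4.32 ± 0.34) were all lower with PSNPs. Trib3 was also among them (−4.28 ± 0.25). The value for Shank1 was −5.63 without PSNPs replicate 2 and −0.825 on the deposited log2 scale, where the pseudocount of 1 understates the change of low genes. On that scale 27 of 102 called named genes had a fold smaller by over 1.5 times and 0 a larger one, and all 102 kept their direction. For these genes of largest change the adjusted p by edgeR's quasi-likelihood test lay between 3.95e-05 and 0.00371.

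Of 18 heat-shock genes, 10 fell and the other 8 did not pass, and 14 were lower adjusted over the list alone. Besides Hspa1a and Hspa1b, Hsph1 fell from 1001 ± 228 to 185 ± 19.4 CPM and Hspb1 from 415 ± 65.2 to 102 ± 22.7 CPM. The list was lower than other genes, with a median log2 fold change of −0.39 and a camera adjusted p of 5.50e-05, but adjusted p = 0.620 with an estimated correlation. Of 31 genes of the unfolded-protein and integrated stress response, 17 fell and 7 rose, with the same counts adjusted over the list alone. The genes that fell were led by Trib3 (−4.28 ± 0.25), Chac1 (a glutathione-degrading enzyme, −3.79 ± 0.23), Mthfd2 (mitochondrial folate metabolism, −2.03 ± 0.15) and the transcription factor gene Atf5 (−1.83 ± 0.13). Among those that rose were Calr (0.87), Pdia4 (0.77), Pdia6 (0.74) and Pdia3 (0.67), chaperones and disulfide isomerases of the endoplasmic reticulum, which were named after their values were seen. The median of the list was −0.60, with a camera adjusted p of 0.0300 and adjusted p = 0.620 with an estimated correlation. Without PSNPs replicate 2 the camera adjusted p was 0.0596 and without PSNPs replicate 3 it was 0.0828, in a range from 0.00613 to 0.620 over 12 alternatives.

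**Figure D1:**
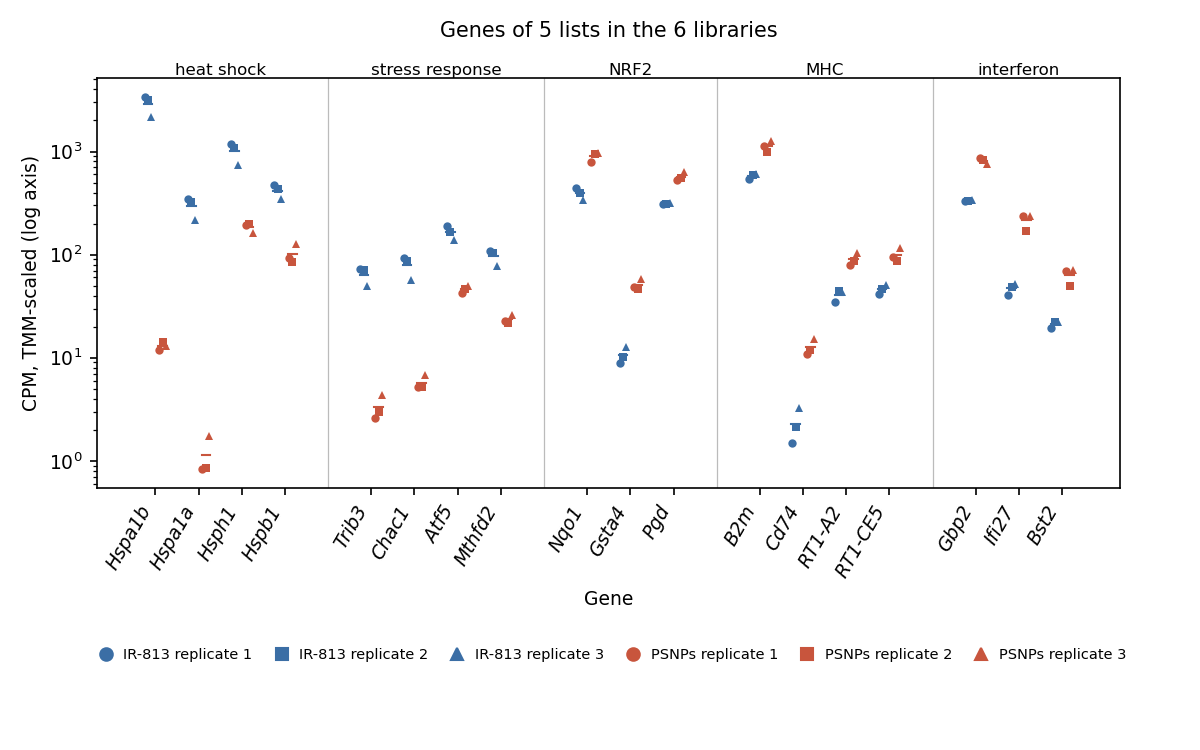
Levels of heat-shock, stress-response, NRF2, MHC and interferon-response genes in each library, in TMM-scaled CPM on a log axis, with a short line at the mean of the 3 libraries of a group (IR-813 blue, PSNPs red). Hspa1b stood at 2903 CPM with IR-813 and 13.02 CPM with PSNPs, and Nqo1 at 392 and 899.6 CPM.

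Markers of astrocytes and oligodendrocytes were abundant in all 6 libraries. The astrocyte gene Gfap ranked between 7 and 18 among all genes and the myelin gene Mbp between 21 and 56, whereas the microglia genes Aif1, Cx3cr1 and P2ry12 ranked between 3796 and 7712, 4568 and 8385, and 9184 and 10894. The median over 8 microglia markers was 62.5 ± 10.3 CPM with IR-813 and 33.0 ± 8.02 CPM with PSNPs (SD over 3 libraries). For the 17 astrocyte markers it was 171 ± 25.4 and 249 ± 34.8 CPM, for the 16 oligodendrocyte-lineage markers 212 ± 18.2 and 79.6 ± 13.2 CPM, and for the 18 neuron markers 17.0 ± 1.47 and 2.16 ± 0.428 CPM. The 17 fibroblast, pericyte and endothelial markers had medians of 1.70 ± 0.329 and 1.24 ± 0.388 CPM, and the 15 infiltrating myeloid and lymphoid markers together stayed at or under 0.605 CPM in every library.

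**Figure D2:**
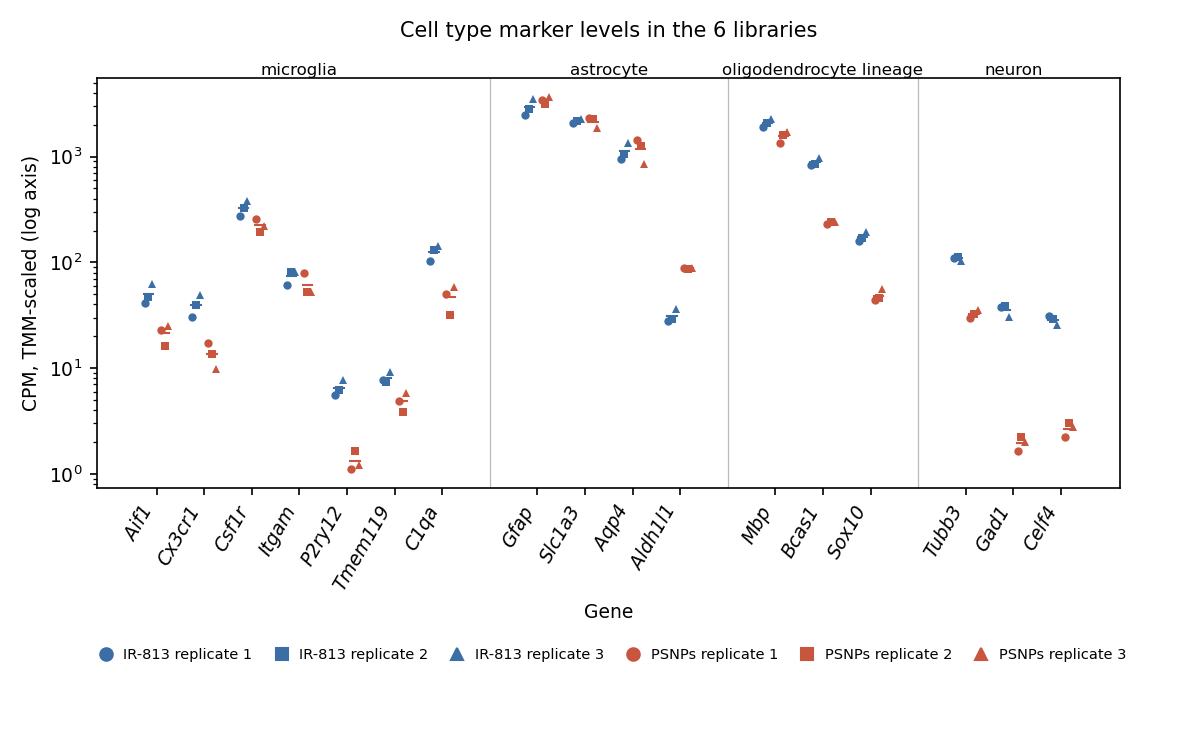
Levels of microglia, astrocyte, oligodendrocyte-lineage and neuron marker genes in each library, in TMM-scaled CPM on a log axis, with a short line at the mean of the 3 libraries of a group (IR-813 blue, PSNPs red). P2ry12 stood at 6.47 CPM with IR-813 and 1.32 CPM with PSNPs, and Gfap at 2949.5 and 3411 CPM.

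Of the 16 oligodendrocyte-lineage markers, 15 fell and Olig1 rose (0.54 ± 0.11, named after its value was seen), with the same counts adjusted over the list alone. Bcas1, a gene of newly formed oligodendrocytes, fell from 882 ± 70.9 to 237 ± 7.01 CPM, and Sox10, a transcription factor gene of the lineage, from 175 ± 17.3 to 48.5 ± 6.64 CPM. Enpp6 fell by 1.77 ± 0.14 and the progenitor gene Cspg4 by 1.45 ± 0.13 on the log2 scale. The list had a median of −0.99 and a camera adjusted p of 5.18e-06, but adjusted p = 0.620 with an estimated correlation. Of 16 tested neuron markers, 12 fell and the other 4 did not pass, and adjusted over the list alone 12 were lower and 1 higher. Besides Gad1, Celf4 fell by 3.42 ± 0.16, the synaptic gene Snap25 by 3.44 ± 0.20 and the tubulin gene Tubb3 by 1.73 ± 0.10. The neuron list had a median of −1.51 and a camera adjusted p of 1.04e-05, with adjusted p = 0.455 with an estimated correlation. Astrocyte markers did not pass as a list (median 0.38, camera adjusted p 0.0722), with 8 members higher and 2 lower of 16, also adjusted over the list alone. Aldh1l1 stood at 31.0 ± 4.32 CPM with IR-813 and 87.9 ± 1.16 CPM with PSNPs, and Fgfr3 at 105 ± 7.51 and 66.2 ± 9.20 CPM, in this list. The camera adjusted p for astrocyte markers was 0.0206 without IR-813 replicate 3, 0.0294 without PSNPs replicate 3, 0.0448 with the length offset and 0.620 with an estimated correlation, and by fry the adjusted p was 0.0453, in a range from 0.0206 to 0.620 over 12 alternatives.

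Of 24 homeostatic microglia genes, 12 fell, 2 rose and 10 did not pass, and 13 fell and 2 rose adjusted over the list alone. The purinergic receptor genes P2ry12 and P2ry13 fell by 2.30 ± 0.22 and 3.46 ± 0.31 on the log2 scale, and the fructose transporter gene Slc2a5 by 3.60 ± 0.38. Siglec5 (−2.45 ± 0.26) and the fractalkine receptor gene Cx3cr1 (−1.54 ± 0.25) also fell. Aif1, which encodes the microglial marker IBA1, fell from 50.4 ± 10.8 to 21.4 ± 4.66 CPM. The homeostatic list had a median of −0.72 and a camera adjusted p of 0.00403, but adjusted p = 0.620 with an estimated correlation. Tmem119 was at −0.74 ± 0.18 with an edgeR adjusted p of 0.0176, which was 0.0527 without IR-813 replicate 1 and 0.0639 without IR-813 replicate 3, in a range from 0.00279 to 0.382 over 19 alternatives. The value for Slc2a5 was −4.27 without PSNPs replicate 2 and −1.40 on the deposited log2 scale. Trem2, a lipid-sensing receptor gene (0.07 ± 0.22), and Cd68, a lysosomal macrophage marker gene (−0.33 ± 0.16), did not pass by edgeR's test, with adjusted p of 0.809 and 0.140.

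Of 6 tested border-associated macrophage markers, 5 fell, also adjusted over the list alone. Siglec1, a sialic acid receptor gene, fell by 3.32 ± 0.22, the chemokine gene Pf4 by 3.09 ± 0.39, the mannose receptor gene Mrc1 by 1.82 ± 0.24 and Cd38 by 0.62 ± 0.12 on the log2 scale. The list had a median of −1.35 and a camera adjusted p of 0.00660, with adjusted p = 0.620 with an estimated correlation. Complement genes split, with 7 higher and 7 lower of 18 and a median of −0.27 (camera adjusted p 0.668), and the same counts adjusted over the list alone. The median of the complement list was −0.52 without PSNPs replicate 1 and −0.12 without IR-813 replicate 3. Cfd stood at −1.83 ± 0.27 and C1qb at −1.75 ± 0.26. Disease-associated microglia genes (8 higher and 5 lower of 26, median 0.08, camera adjusted p 0.261) included Lyz2 at 2.83 ± 0.19 and B2m at 0.97 ± 0.12. Phagocytosis and scavenger receptors (5 higher and 9 lower of 28, or 6 and 10 adjusted over the list alone, median −0.25, camera adjusted p 0.616) included Gas6, a ligand of phagocytic receptors, at 1.59 ± 0.12 and Cd36.

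Of 22 genes of MHC antigen presentation, 17 rose and the other 5 did not pass, also adjusted over the list alone. Cd74 rose by 2.46 ± 0.29, the class I genes RT1-A2 and RT1-CE5 by 1.14 ± 0.14 and 1.09 ± 0.13, and B2m, the class I light chain, from 579 ± 33.5 to 1134 ± 143 CPM. Class I genes form a family of similar copies, so their split is uncertain. The list had a median of 1.03 and a camera adjusted p of 3.70e-05, but adjusted p = 0.620 with an estimated correlation. Of 32 interferon-response genes, 9 rose, 1 fell and 22 did not pass, also adjusted over the list alone. Ifi27 rose by 2.19 ± 0.16, Bst2, which tethers virus particles, by 1.57 ± 0.16, and the GTPase gene Gbp2 by 1.28 ± 0.08, while Ifi27l2b fell by 1.69 ± 0.22. This list had a median of 0.71 and a camera adjusted p of 0.00272, with adjusted p = 0.620 with an estimated correlation. Its median was 1.14 without IR-813 replicate 3, 0.47 without IR-813 replicate 1 and 0.41 without PSNPs replicate 1, and it did not pass by fry (adjusted p 0.0758, in a range from 1.93e-05 to 0.620 over 12 alternatives).

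Inflammatory mediators went both ways. Of 24 tested pro-inflammatory cytokines and chemokines, 11 rose and 4 fell (11 and 6 adjusted over the list alone), with a median of 0.40 and a camera adjusted p of 0.0946. Nos2, the inducible nitric oxide synthase gene, was at 0.230 ± 0.0816 CPM with IR-813 and 4.68 ± 1.44 CPM with PSNPs, and the chemokine gene Ccl5 at 1.13 ± 0.184 and 9.44 ± 1.01 CPM. The cytokine genes Il1b (0.50 ± 0.43) and Ccl2 (0.30 ± 0.15) did not pass by edgeR's test, with adjusted p of 0.377 and 0.145. Il6 had between 0 and 3 counts and Tnf between 1 and 5 counts per library, too few for the test. The median of the cytokine list was 0.20 without PSNPs replicate 1, 0.61 without PSNPs replicate 2, 0.75 without IR-813 replicate 3 and 0.25 with the length offset. Its camera adjusted p was 0.0307 without IR-813 replicate 2, 0.0240 without PSNPs replicate 2 and 0.0439 with library size only, and by fry the adjusted p was 0.0139, in a range from 0.0139 to 0.620 over 12 alternatives.

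Of 23 NF-kB feedback and target genes, 11 rose and 2 fell, also adjusted over the list alone. The inhibitor genes Nfkbia, Nfkbiz and Tnip1 rose by 0.74 ± 0.10, 1.02 ± 0.12 and 0.80 ± 0.08, and Cd83 by 0.98 ± 0.14. Their list had a median of 0.30 and a camera adjusted p of 0.0185, but adjusted p = 0.620 with an estimated correlation, and 0.0934 without PSNPs replicate 3, in a range from 0.00481 to 0.620 over 12 alternatives. Inflammasome components (3 higher and 6 lower of 14, also adjusted over the list alone, median −0.28, camera adjusted p 0.258) included Casp4 at −1.69 ± 0.13 and the interleukin-1 receptor antagonist gene Il1rn at 2.79 ± 0.29. Alternative activation and anti-inflammatory genes (5 higher and 5 lower of 14, or 5 and 6 adjusted over the list alone, camera adjusted p 0.824) had a median of 0.03 and a mean of −0.13, with a downward test, and included Vegfa at −1.77 ± 0.13.

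Of 29 NRF2 oxidative-stress genes, 16 rose and 6 fell, also adjusted over the list alone. The glutathione transferase gene Gsta4 rose from 10.6 ± 1.95 to 51.0 ± 6.28 CPM, Nqo1 by 1.20 ± 0.13, and the pentose phosphate pathway gene Pgd by 0.87 ± 0.09 on the log2 scale. The members that fell were Osgin1 (−1.15), the heme oxygenase gene Hmox1 (−1.07), the thioredoxin reductase gene Txnrd1 (−0.93), Sqstm1 (−0.70), Srxn1 (−0.58) and Gclc (−0.37), named after their values were seen. The list had a median of 0.41 and a camera adjusted p of 0.0185, but adjusted p = 0.620 with an estimated correlation. Its camera adjusted p was 0.0568 without IR-813 replicate 3 and 0.101 with the length offset, where the median was 0.07, in a range from 0.00738 to 0.620 over 12 alternatives. Of 26 genes of cholesterol biosynthesis, 11 rose and the other 15 did not pass, also adjusted over the list alone. Tm7sf2 (1.33 ± 0.15), Ebp (0.94 ± 0.14), Pmvk (0.67 ± 0.11) and Msmo1 (0.65 ± 0.08), all enzymes of the pathway, rose. The cholesterol list had a median of 0.31 and a camera adjusted p of 0.00297, with adjusted p = 0.620 with an estimated correlation.

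Genes of oxidative phosphorylation and ribosomal proteins had small shifts, which were largest in PSNPs replicate 3. Of 36 genes of oxidative phosphorylation, 11 rose by edgeR's test (median 0.31, camera adjusted p 0.000666), and of 44 ribosomal protein genes 3 rose (median 0.27, camera adjusted p 0.00237). With an estimated correlation these were adjusted p = 0.620 and adjusted p = 0.688, and neither list passed by fry (adjusted p 0.126 and 0.237). Without PSNPs replicate 3 the medians were 0.16 and 0.08, with camera adjusted p of 0.00260 and 0.0237, in ranges from 7.93e-05 to 0.620 and from 8.05e-05 to 0.688 over 12 alternatives. Adjusted over the list alone, 0 genes passed by edgeR's test in either list, while 19 and 6 had an unadjusted p under 0.05. Ndufa2, Ndufs3 and Cox7c, subunits of the respiratory chain, were at 0.69 ± 0.17, 0.52 ± 0.13 and 0.44 ± 0.11, and Rpl37, Rpl11, Rps4x and Rpl19 at 0.50 ± 0.15, 0.48 ± 0.15, 0.42 ± 0.13 and 0.40 ± 0.14, of which Rpl19 did not pass (edgeR adjusted p 0.0604). The calls of Ndufa2 and Cox7c were lost without IR-813 replicate 1 and without replicate 2, and those of Ndufs3, Rpl11, Rpl37 and Rps4x without any 1 of the IR-813 libraries. For Ndufs3 the edgeR adjusted p was 0.0690, 0.0795 and 0.0591 without IR-813 replicates 1, 2 and 3, in a range from 0.000628 to 1.00 over 19 alternatives, and for Rpl37 it was 0.110, 0.109 and 0.0900, in a range from 0.00453 to 1.00. The median shift of the 80 members from the IR-813 mean was 0.12, 0.09 and 0.58 in PSNPs replicates 1, 2 and 3, and with the length offset the median of the ribosomal protein list turned to −0.07.

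**Figure D3:**
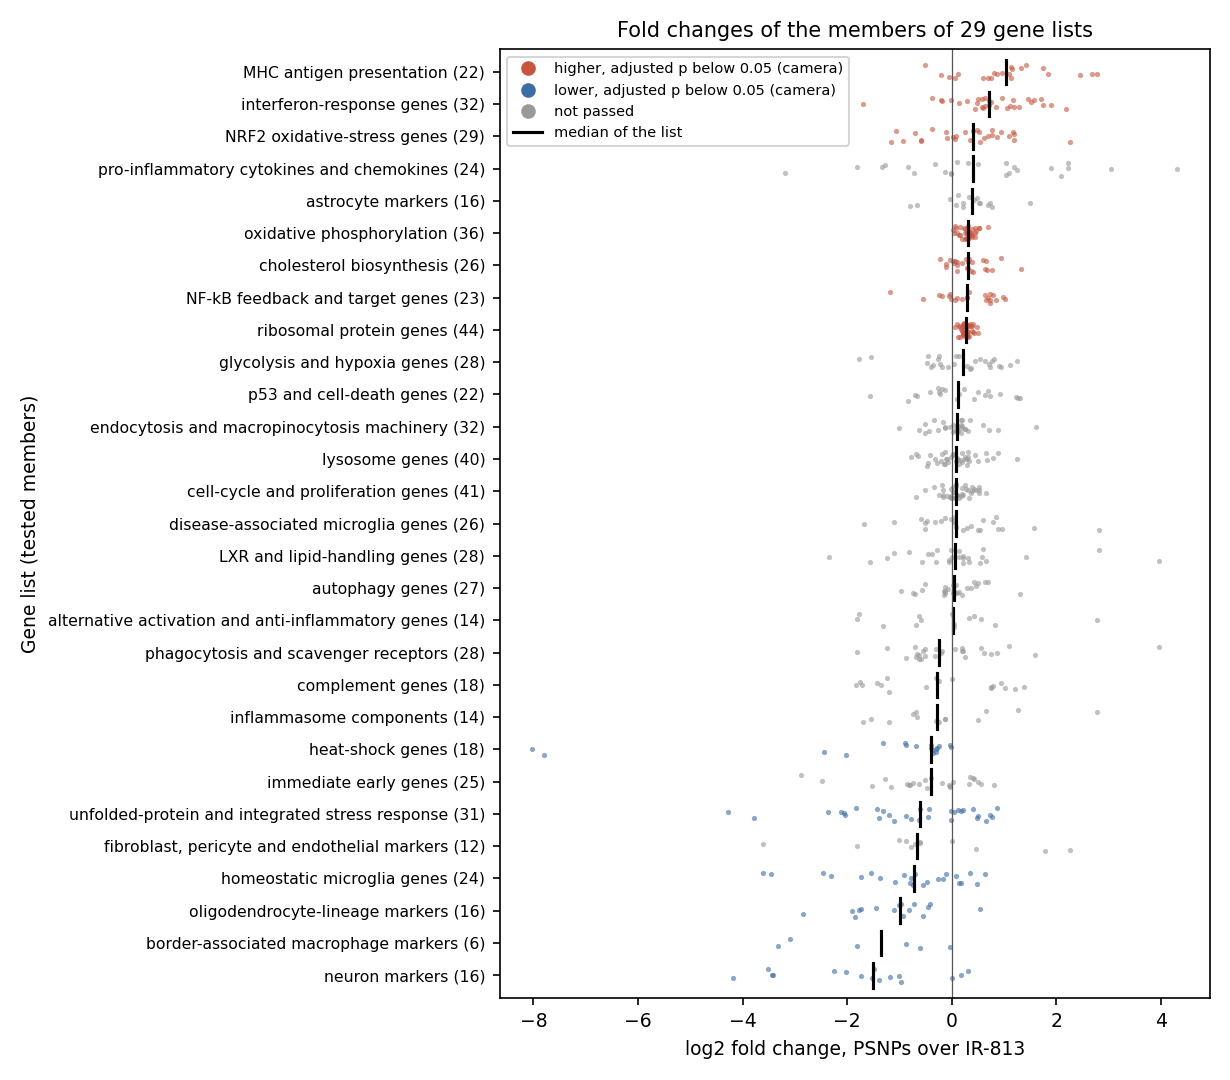
Log2 fold changes (PSNPs over IR-813) of the tested members of 29 gene lists, 1 point per gene, with a black line at the median of each list, coloured by whether the list passed camera with a preset correlation. Medians ran from −1.51 for neuron markers to 1.03 for MHC antigen presentation, and the ribosomal protein list, higher here, turned to −0.07 with the length offset.

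The remaining lists did not pass camera. Immediate early genes (6 higher and 12 lower of 25, or 7 and 12 adjusted over the list alone, median −0.40, camera adjusted p 0.0976) included the phosphatase genes Dusp5 at −2.88 ± 0.24 and Dusp1 at −2.48 ± 0.19, and passed without IR-813 replicate 3 (camera adjusted p 0.0206, in a range from 0.0171 to 0.620). Endocytosis and macropinocytosis genes (7 higher and 2 lower of 32, median 0.10, camera adjusted p 0.244) included the caveolin gene Cav1 at 1.61 ± 0.07 and Flot2 at 0.88 ± 0.10. Lysosome genes (9 higher and 4 lower of 40, median 0.09, camera adjusted p 0.346) included Gla at 0.66 ± 0.09, and autophagy genes (7 higher and 4 lower of 27, median 0.05, camera adjusted p 0.484) Wipi1 at 1.30 ± 0.10 and Bnip3l at 0.70 ± 0.08. LXR and lipid-handling genes (7 higher and 6 lower of 28, median 0.07, camera adjusted p 0.690, with an upward camera test and a downward fry test) included Apoc1 at −2.35 ± 0.21 and the triglyceride synthesis gene Dgat2 at −1.56 ± 0.10. These counts were the same adjusted over the list alone.

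Glycolysis and hypoxia genes (12 higher and 4 lower of 28, or 13 and 5 adjusted over the list alone, median 0.21, camera adjusted p 0.15) included the hypoxia-induced hydroxylase gene Egln3 at 1.25 ± 0.10 and Vegfa. Cell-cycle and proliferation genes (8 higher and 2 lower of 41, or 7 and 2 adjusted over the list alone, median 0.09, camera adjusted p 0.15) included Rrm2 at 0.53 ± 0.08 and Kif20a at 0.52 ± 0.08. In p53 and cell-death genes (9 higher and 3 lower of 22, also adjusted over the list alone, median 0.12, camera adjusted p 0.237) the death receptor gene Fas was at 1.31 ± 0.13 and Ccng1 at 1.23 ± 0.08. The median of this list was −0.00078 without IR-813 replicate 3. In fibroblast, pericyte and endothelial markers (2 higher and 4 lower of 12, or 2 and 6 adjusted over the list alone, median −0.66, camera adjusted p 0.217) the smooth-muscle actin gene Acta2 was at −3.60 ± 0.24 and the VEGF receptor gene Flt1 at 2.27 ± 0.19. Of the lists that did not pass camera, those of autophagy, endocytosis, glycolysis and hypoxia, immediate early and p53 genes passed by fry, besides astrocyte markers and cytokines, with adjusted p of 0.00887, 0.00341, 0.00430, 0.0171 and 0.00509. Leaving out 1 library also moved medians by over 1.5 times for inflammasome components (−0.44 without PSNPs replicate 2), phagocytosis and scavenger receptors (−0.13 without PSNPs replicate 2), disease-associated microglia genes (0.21 without PSNPs replicate 2) and cell-cycle genes (0.14 without IR-813 replicate 3), and for lists with a median near 0. By camera with the preset correlation 7 lists were higher and 6 lower of 29. With an estimated correlation 0 passed, where 1 list had an unadjusted p under 0.05. By fry, which does not compare a list with the other genes, 17 lists passed.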

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

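The length offset and the fit without ribosomal RNA genes were chosen after the data had been seen. The gene counts stayed within 1.5 times the reported 2439 higher and 2351 lower genes under each scaling, DESeq2, limma-voom, both other count filters, the deposited log2 values, the length offset (2760 and 2735) and the fit without ribosomal RNA genes. The stricter thresholds gave 533 higher and 872 lower genes against a 1.5-fold change and 1279 and 1351 at an adjusted p under 0.01, since they ask for more by construction. Leaving out 1 library gave between 1339 and 3591 higher and between 1473 and 3478 lower genes. The lowest counts came without IR-813 replicate 2 (1339 and 1473) and without IR-813 replicate 1 (1416 and 1571), and the highest without PSNPs replicate 3, and the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower by camera, against 7 and 6 with the preset one. With the length offset the median of the ribosomal protein list reversed to −0.0738 (camera adjusted p 0.279), as the offset removes a trend along length. Whether the same numbers pair the samples was not settled. The correlations of deviations of same-numbered libraries were −0.00585, 0.0145 and 0.121. With 3 libraries per group these deviations depend on each other, so the values cannot exclude a pairing. The replicate block gave 2035 higher and 2124 lower genes and 8 and 6 lists, with the astrocyte markers as the added list (camera adjusted p 0.0491, in a range from 0.0206 to 0.620 over 12 alternatives), and 2 of the 6 libraries correlated best with their own number.

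Of 107 tested named genes, 87 kept their call under all 19 alternatives. Over 2033 combinations of named gene and alternative, 1968 calls were kept, 60 were lost, 5 were gained and 0 turned direction. Over 348 combinations of list and alternative, 310 calls were kept, 22 were lost, 15 were gained and 1 turned direction, the ribosomal protein list with the length offset. Of the 4790 called genes, between 1405 (against a 1.5-fold change) and 4789 (without ribosomal RNA genes) were called in the same direction under an alternative. At this depth 11679 of 16876 gene symbols passed the count filter, against 14018 tested without a filter (2443 higher and 2366 lower genes). The share of 15.0% of simulated 1.5-fold changes that was recovered holds for 100 genes changed 2-fold and 100 changed 1.5-fold, and says little of the real comparison, where 4790 genes were called and the adjusted threshold was less strict.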

Other observations

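Of the tests below, those of the xenobiotic-metabolism families, of a uniform loss of each cell type, of RNA from other glial cells and of reads shared by Hspa1a and Hspa1b were chosen after the result was seen, as was the length offset.

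Genes of xenobiotic metabolism were frequent among the increases. Ephx1, the microsomal epoxide hydrolase gene, rose from 35.7 ± 4.06 to 263 ± 19.8 CPM (SD, n = 3 each), Mgst1 from 11.0 ± 0.712 to 47.0 ± 6.42 CPM, Ugt1a7c from 41.4 ± 3.06 to 162 ± 10.5 CPM, Gsta1 from 120 ± 10.3 to 368 ± 40.7 CPM and Cyp1a1 from 4.21 ± 0.710 to 18.3 ± 1.23 CPM. Cyp4b1 fell from 84.8 ± 16.2 to 7.40 ± 1.78 CPM. These genes were picked after Mgst2 and Ptgr1 had been seen among the largest increases, and members of the Ugt1a and Gst families share sequence, so their split is uncertain.

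The hypothesis that such families rose as a set was tested on genes taken by the start of their symbol, for cytochromes P450, epoxide hydrolases, glutathione, UDP-glucuronosyl and sulfotransferases, quinone, aldo-keto and prostaglandin reductases, aldehyde dehydrogenases and oxidases, flavin monooxygenases, carboxylesterases and Abcc transporters. The prefixes took subfamilies, so that 14 tested genes of these families, such as Aldh2, Aldh1l1, Cyp51 and Ugt8, were outside the set. Of 87 tested genes, 47 rose and 14 fell by edgeR's test, with a median log2 fold change of 0.64. The camera p was 1.787e-06, and p = 0.0199 with an estimated correlation. All p-values of this set and its variants are unadjusted, unlike those of the lists. With an estimated correlation the neuron markers had a camera p of 0.0157 before adjustment over the 29 lists and 0.455 after it. The values of the xenobiotic set include the genes that prompted the test. Without Mgst2 and Ptgr1 the camera p was 6.01e-06 (median 0.58, 85 genes), without their families 1.64e-05 (median 0.54, 82 genes) and without the 10 members whose values the text gives 0.000140 (median 0.45, 77 genes, 38 higher and 13 lower), with p = 0.0204, p = 0.0180 and p = 0.0176 with an estimated correlation. The choice of families still came after the largest increases had been seen. With the whole families, added after the values were seen, 53 of 101 genes rose and 16 fell (median 0.48, camera p 6.28e-07, and p = 0.0255 with an estimated correlation). Taken by symbol alone, this set also held Fmod, which encodes the matrix protein fibromodulin, and 7 cytochromes P450 of the families numbered 20 and above. Fmod was noticed after the values were seen, and without it p was 7.69e-07 (median 0.68, 86 genes), while without Fmod and those cytochromes p was 2.61e-07 (median 0.76, 79 genes, 46 higher and 12 lower). Leaving out the genes shared with the list of oxidative-stress genes gave the set as first tested a median of 0.54 and a camera p of 9.61e-06. The length offset gave it a median of 0.52 and a camera p of 6.22e-06.

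The ribosomal protein and oxidative phosphorylation lists were higher with PSNPs by a median of 0.29 over 80 members (quartiles 0.21 and 0.36) and passed camera with a preset correlation, but had adjusted p = 0.688 and adjusted p = 0.620 with an estimated correlation. The length proxy of these genes lay at a median percentile of 3.95 among tested genes, and across genes, which are not independent, the proxy had a Spearman correlation of −0.324 with the fold change, −0.590 with the difference of PSNPs replicate 3 from replicates 1 and 2, and −0.194 with the difference of those replicates from IR-813. With a length offset the median was −0.02315 (quartiles −0.11 and 0.11). The camera calls ended (adjusted p 0.279 and 0.384), because the fold itself fell to near 0. The offset was fitted in each library without regard to treatment, so it removes a shift of short genes whatever its cause. A length-dependent yield of the libraries may account for the shift, but the offset cannot tell it from an effect of the treatment. Without PSNPs replicate 3 the median was 0.11 (quartiles 0.04 and 0.19) with camera adjusted p of 0.0237 and 0.00260, which leaves open whether that library alone carried the shift. An effect of PSNPs on short transcripts was not tested apart from this.

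Astrocyte and oligodendrocyte-lineage transcripts were abundant in libraries labelled microglia, and RNA from other glial cells of the mixed cultures may account for them. In each of the 6 libraries, 15 of 17 astrocyte and 15 of 16 oligodendrocyte-lineage markers stood at 5 CPM or more, and the astrocyte markers summed to between 9.78 and 22.6 times the 8 microglia markers. Gfap stood at 2949.5 ± 545 and Slc1a3 at 2176 ± 77.5 CPM with IR-813, 0 of the genes of these lists and of the neuron list were held by another list, the labels name shaking but no sort that would remove such cells, and how many of them microglia express was not counted. An equal loss of all cells of a type would lower its markers by 1 factor, if no other cells expressed them. The fold changes differed by more than their errors in the oligodendrocyte-lineage markers (Cochran's Q 524.3 on 15 degrees of freedom, range −2.84 to 0.54). They also did in the neuron markers (Q 907.1 on 15, range −4.19 to 0.32) and the homeostatic and marker genes of microglia (Q 778.2 on 26, range −3.60 to 0.63). These values argue only against such an equal loss as the whole cause. The lists mix stages of a lineage, such as Bcas1 and Cspg4, and other cells may express some members. A loss of some of the cells of a type is therefore not excluded. A change in cell shares together with a change inside the cells, and an effect of PSNPs itself, stay open.

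Of 18 heat-shock genes 10 fell and 8 did not pass, and the list was lower by camera with a preset correlation (adjusted p 5.50e-05) but not with an estimated one (adjusted p = 0.620), with IR-813 holding high levels of Hspa1b. Reads shared by Hspa1a and Hspa1b would touch those genes alone, yet 8 of the other 16 tested members also fell (median of the 16, −0.38). That argues against shared reads as the whole cause of the lower list. Sharing would move reads between these copies, but both fell. Hspa1b went from 2903 CPM with IR-813 to 13.02 CPM with PSNPs, and Hspa1a from 294 to 1.13 CPM. A difference in handling between the 2 sets of cultures cannot be told apart from the treatment, since the immediate early genes, which handling also induces, had a median of −0.40 with a camera adjusted p of 0.0976 and members on both sides. No library labelled untreated was analysed here, so a rise with IR-813 cannot be told from a fall with PSNPs.

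The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2439 higher and 2351 lower genes and each of the other splits 0 by edgeR's test, with 5921 genes at an unadjusted p under 0.05 in the real split and between 5 and 244 in the others. As many genes in either direction came from 1 of the 10 splits, the real one. For lists, 6 of the 10 splits gave at least 7 in 1 direction and 7 gave at least 6, with 13 the highest in any other split against the real 7 higher and 6 lower. Each other split sets 2 libraries of 1 treatment and 1 of the other against the rest. The treatment difference, along a first principal component with 77.4% of the variance, then widens the spread within each side. That alone can leave 0 gene calls, so the 0 of the other splits is no evidence on what caused the real calls. Such a split also carries part of the treatment difference between its sides. Its list calls therefore do not tell the treatment from another structure of the samples.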
